A study of Homo sapiens with 4 samples.

How the data were processed

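Total RNA of 4 samples was measured on Illumina bead arrays, 2 arrays of the breast cancer line SUM-44 and 2 arrays of MCF10A-WHSC1L1s, a line made from the immortalised breast epithelial line MCF10A by lentiviral transfer of the short isoform of WHSC1L1 (current symbol NSD3). RNA was extracted with a column kit, checked for quality and labelled with biotin after amplification, per the labels' protocols. Groups and replicate numbers were taken from the labels. Nothing in the labels says that the replicates came from separate cultures, so the p-values of genes measure only the spread between these samples, which may be technical. The p-values of gene lists and of runs of neighbouring genes compare genes with other genes and do not measure spread between samples.

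The values used are the deposited log2 intensities of 22177 probes. The 4 arrays have the same sorted values to within 0.000934 and a median of 7.26, as quantile normalization leaves them, and the normalization method and software are not given in the sources used here. The log base was inferred from the deposited values: the brightest probe, 15.77, would be an intensity of 55719 in base 2 and 7031249 in base e, and a 16-bit scanner ends at 65535. The deposited values keep a background mode at 6.93 on the log2 scale, so no background appears to have been subtracted, which compresses differences between dim probes. A second table with 4 columns of signal, each with a detection p-value, was not used here, since its column names match no sample. The tests planned before the data were examined assumed that table, with background correction from detection p-values. The deposited log2 values took its place, with no further normalization, and a limit on brightness took the place of the detection p-values.

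That limit was chosen after the data were seen. The part of the distribution below its mode was mirrored, and its 99th percentile, 7.30 on the log2 scale, was taken as the upper end of background. On each array 10784 probes lay above it. A probe was tested when it was above background on both arrays of at least 1 line, which kept 11552 probes of 9693 genes and left out 10625 probes. A gene not above background on either array of a line is given as at least N-fold, the mean of the bright line over the background limit. Probes were named from the platform annotation, in which 19708 probes have 1 gene symbol, 0 have several and 2469 are not listed. The Entrez genes of 19688 probes were found in the RefSeq table of assembly GRCh38.p14, and 0 symbols changed. That table was used only for names and for the order of genes. A gene with several probes was represented by its brightest tested probe. Of the 781 genes with over 1 tested probe, 14 had probes past the threshold in opposite directions. Of these, 0 are among the 120 genes named by the fixed rule below, and other genes named were not checked.

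Differences are SUM-44 minus MCF10A-WHSC1L1s. They were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 4 arrays, with the line as the only term, 2 residual and 3.46 prior degrees of freedom. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all tested probes. Every adjusted p of a gene comes from this fit unless another setting is named beside it. The number of arrays, 2 per line, limits the precision. A simulation of 11552 probes held 50 probes with a difference of each size and no difference elsewhere. There the fit called 0% of differences of 0.5 on the log2 scale, 72% of 1, and 100% of 2 and 4. Of all calls there, 5.6% were false. Far more probes, 6297, passed in the data, which loosens the adjusted threshold, so these shares do not carry over to the data. Tables and figures were made in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

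A total of 23 gene lists, fixed before the data were examined, hold 544 entries, of which 485 have a probe and 18 of those were matched through an older symbol. They cover the 8p11-12 region, the neighbouring proximal 8p11.2 region, the 9p21 region, basal and myoepithelial markers, keratinocyte differentiation, oestrogen receptor and luminal identity, luminal keratins and secretory markers, epithelial junctions, mesenchymal and matrix genes, EGF receptor and MAPK response, FGF receptor signalling, H3K36 methylation enzymes, cell cycle, cell cycle inhibitors and p53 targets, interferon response, inflammatory cytokines, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, NRF2 response and glutathione, housekeeping, cancer-testis antigens, and stromal, endothelial and immune markers. Some genes are in more than 1 list, among them NSD3, FGFR1, CDKN2A and CDKN2B. Lists with at least 3 tested genes, 22 of them, were set against all other genes with camera at a preset correlation of 0.01, adjusted over the 22 lists, and again with the correlation estimated from the data. In a simulated comparison a list shifted by 1 on the log2 scale had an adjusted p of 1.28e-40 with the preset correlation and 0.264 with an estimated one, so the second form did not call the shifted list. The simulated genes were independent and no other list was shifted, which favours the preset form. In the data the estimated correlations of the lists ran from -0.089 to 0.641, so the simulation cannot decide between the forms. The oestrogen receptor and luminal identity list had an estimated correlation of -0.039, below the preset. Its camera p still rose from 3.98e-09 to 0.023, which is 0.46 after adjustment. A call lost under the second form is therefore no evidence that the genes of a list are correlated. The p of the second form is given beside each call.

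The genes named follow a rule fixed before the data were examined: WHSC1L1, ESR1, FGFR1, EGFR and CDH1 whatever their values, the 10 genes with the largest differences past the threshold in each direction among those whose lines do not overlap, and for each list up to 4 members past the threshold with the largest differences and up to 2 past it in the direction opposite to most. Further members that make up a small count are named without a value, and were chosen after their values were seen. Genes named with values for a difference between replicates, and genes named in runs of neighbours, may lie outside this rule. They were also chosen after the data were seen. Alternatives changed 1 choice at a time: the background correction, scaling, the filter on dim probes, the replicate number as a block, an intensity trend in the variance, a minimum difference tested within the model, the probe of a gene, and leaving out each array. With 1 array left in a line, that array was assumed to vary like the other line. A call lost there can therefore come from the spread of the other line and not from the array left out. Arrays of parental MCF10A were not analysed here.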

Results

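The study asked which genes change when WHSC1L1, a histone methyltransferase gene of the chromosome 8p11-12 region that is amplified in some breast cancers, is raised in MCF10A cells, and which of those also differ in SUM-44 cells. SUM-44 is a breast cancer line labelled as carrying amplified WHSC1L1, and MCF10A is an immortalised, non-cancerous breast epithelial line. The study's own comparisons are each against parental MCF10A, which was not analysed here. The 4 arrays analysed, 2 of SUM-44 and 2 of MCF10A-WHSC1L1s, allow 1 comparison, between 2 lines that were both chosen for raised WHSC1L1. It answers how the lines differ, not what WHSC1L1 does. The media differed as well: that of MCF10A-WHSC1L1s held 10 ng/ml EGF and blasticidin, and that of SUM-44 lists neither. Insulin is recorded for MCF10A-WHSC1L1s, and no amount is recorded for SUM-44.

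Over the 11552 tested probes the 2 SUM-44 arrays correlated at r = 0.985 and the 2 MCF10A-WHSC1L1s arrays at r = 0.992, against 0.789 to 0.797 between lines. These correlations are across probes, which are not independent replicates. The SD of the difference between replicates was 0.304 on the log2 scale in SUM-44 and 0.229 in MCF10A-WHSC1L1s, and between lines it was 1.13 to 1.16. No array was a copy of another.

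WHSC1L1 was higher in SUM-44 than in the line transduced with it. The probe for the short-isoform transcript record read 10.02 ± 0.20 in SUM-44 and 7.82 ± 0.16 in MCF10A-WHSC1L1s (mean log2 intensity ± SD, n = 2 arrays each), a 4.57-fold difference (log2 difference 2.19, SE 0.15, limma adjusted p = 0.000226). The 2 probes for the long-isoform record differed by 1.34 (adjusted p = 0.00124) and 1.28 (adjusted p = 0.00105). In MCF10A-WHSC1L1s the long-isoform probes lay near background, at 7.40 and 7.41, the second above it on 1 of 2 arrays. Whether the probes lie within the transduced sequence is not given in the sources used here, so they do not check the labels. ESR1, the oestrogen receptor, was at least 37.1-fold higher in SUM-44 (adjusted p = 7.11e-06) and was not above background in MCF10A-WHSC1L1s. FGFR1, an 8p11-12 gene, was at least 1.85-fold higher in SUM-44 by 1 probe (adjusted p = 0.00146), and its other probe was not above background in either line. EGFR was at least 4.62-fold lower in SUM-44 (adjusted p = 0.000157) and not above background there. Of its other probes, 1 was at least 1.53-fold lower (adjusted p = 0.00108), also not above background in SUM-44, and the rest were not above background in either line. CDH1, E-cadherin, read 7.15 ± 0.07 in SUM-44, not above background, and 7.47 ± 0.05 in MCF10A-WHSC1L1s, a difference that did not pass the threshold (adjusted p = 0.0534). It passed with background correction (0.0337), with no filter (0.0439) and with an intensity trend (0.0166).

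**Figure D1:**
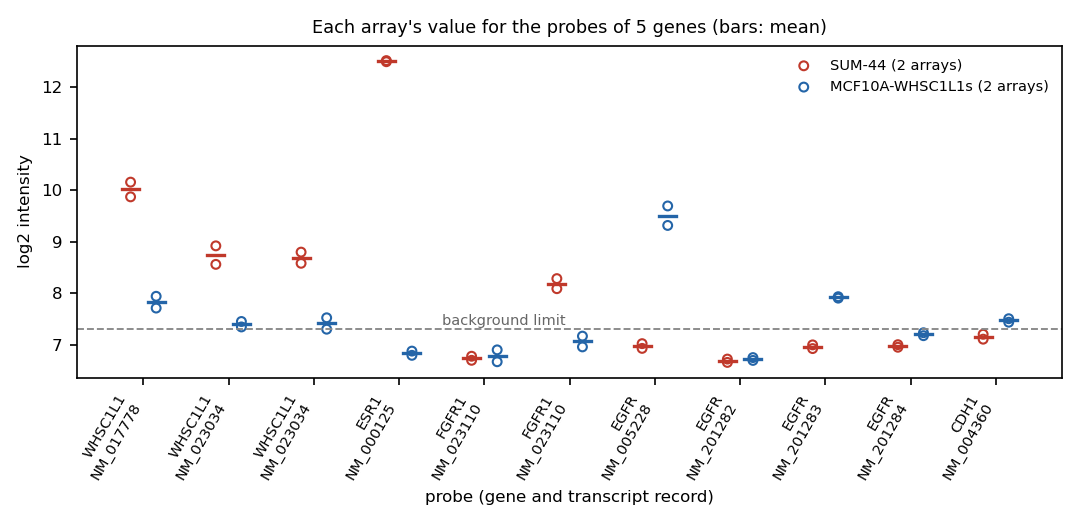
Log2 intensity of each array (points) and the mean of each line (bars) for the probes of WHSC1L1, ESR1, FGFR1, EGFR and CDH1, named by transcript record, with the background limit at 7.30 as a dashed line. All WHSC1L1 points of SUM-44 lie above those of MCF10A-WHSC1L1s, and the ESR1 points of SUM-44 are near 12.51.

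Of 9693 tested genes, 2614 were higher and 2765 lower in SUM-44, and 1167 and 1026 of these differed by at least 2-fold. At an unadjusted p of 0.05, 7053 of the 11552 probes passed. Above background on both arrays of SUM-44 and on neither of MCF10A-WHSC1L1s, or the reverse, were 702 and 630 probes. Without MCF10A-WHSC1L1s replicate 1 the counts fell to 1672 higher and 1714 lower genes, and without MCF10A-WHSC1L1s replicate 2 to 1604 and 1567.

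The genes furthest above MCF10A-WHSC1L1s included several secreted products of luminal breast epithelium. TFF3, a trefoil factor, was at least 291-fold higher (adjusted p = 5.55e-06) and MUCL1, a small breast mucin, at least 354-fold. MUCL1 was the brightest probe on the SUM-44 arrays, so its value may sit at the ceiling. SCGB2A2 (mammaglobin) was at least 122-fold higher and PIP (prolactin-induced protein) at least 101-fold. IGFBP5, the growth factor midkine (MDK), THRSP and IFI27 were at least 129.6-, 129-, 85.0- and 83.8-fold higher. APOD, above background on 1 of 2 MCF10A-WHSC1L1s arrays, differed by 8.06 and CRIP1 by 7.65. The largest of the adjusted p-values of these 10 genes was 4.53e-05.

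Those furthest below were mostly basal and squamous epithelial genes. KRT15 differed by -7.83 (SE 0.15, adjusted p = 7.11e-06) and was above background on 1 of 2 SUM-44 arrays. GSTP1, a glutathione transferase, was at least 167-fold lower, S100A2 at least 114-fold, and the basal keratins KRT5 and KRT16 at least 83.3- and 82.3-fold. KRT6C was at least 102-fold lower, though near-identical keratin 6 copies make its probe uncertain. DKK1, a secreted Wnt antagonist, CAV2 and PHACTR3 were at least 94.9-, 57.7- and 56.6-fold lower, and ANXA1 differed by -6.24. The largest of these 10 adjusted p-values was 1.42e-05.

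Luminal identity separated the lines. Of 22 tested genes of oestrogen receptor and luminal identity, 19 were higher in SUM-44, 0 were lower (also 0 at an unadjusted p of 0.05) and 3 did not pass (GATA3, STC2 and CCND1), with the same counts adjusted over the list alone and a median of 1.96 on the log2 scale (camera adjusted p = 4.38e-08, and adjusted p = 0.46 with an estimated correlation). GATA3 read 8.00 and 10.60 on SUM-44 replicates 1 and 2, against 7.81 and 7.90 in MCF10A-WHSC1L1s. TFF1, an oestrogen-regulated secreted peptide, was at least 74.1-fold higher and carbonic anhydrase CA12 differed by 5.53. Without SUM-44 replicate 2, 1 member, STC2, passed as lower. Of 12 luminal keratins and secretory markers, 8 were higher, 2 lower and 2 did not pass, also adjusted over the list alone (camera adjusted p = 0.00849, and adjusted p = 0.479 with an estimated correlation). KRT19 differed by 5.84, while KRT7 differed by -3.17 (adjusted p = 0.000234) and the mucin MUC1 by -0.47 (adjusted p = 0.0153, and 0.0843 and 0.093 without MCF10A-WHSC1L1s replicate 1 or 2, which leaves 1 member lower). The list missed the threshold over genes above background on all 4 arrays (0.119).

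Basal and keratinocyte genes went the other way. Of 19 basal and myoepithelial markers 17 were lower in SUM-44 and 2 higher, also adjusted over the list alone, with a median of -4.03, or -3.36 with the 10 genes not above background in 1 line at their bounds (camera adjusted p = 2.76e-08, and adjusted p = 0.46 with an estimated correlation). The higher members were CD44, a hyaluronan receptor (0.62, adjusted p = 0.0073), and MYLK, at least 1.38-fold and not above background in MCF10A-WHSC1L1s (adjusted p = 0.01). Without MCF10A-WHSC1L1s replicate 1 neither passed (0.0593 and 0.0765), leaving 0 higher members, and without MCF10A-WHSC1L1s replicate 2 MYLK did not (0.0584), leaving 1. Of 21 keratinocyte differentiation genes 17 were lower, 3 higher and 1 did not pass, also adjusted over the list alone (camera adjusted p = 0.000381, and adjusted p = 0.479 with an estimated correlation). SERPINB5 (maspin) differed by -5.60, with 1 of 2 SUM-44 arrays above background, and the kallikrein KLK5 by -4.65. The kallikrein KLK7 and CSTA, not above background in SUM-44, were at least 29.9- and 6.24-fold lower (KLK7 at least 17.95- and 49.7-fold without MCF10A-WHSC1L1s replicate 1 or 2), whereas the calcium-binding S100A8 and CALML5 were higher, by 2.17 and 1.87, as was S100A7. Over genes above background on all 4 arrays the keratinocyte list missed the threshold (0.164).

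Matrix and junction genes were mostly lower in SUM-44. Of 17 mesenchymal and matrix genes 11 were lower, 2 higher and 4 did not pass, also adjusted over the list alone (camera adjusted p = 0.000504, and adjusted p = 0.46 with an estimated correlation). COL8A1, TGFBI and the collagen cross-linking enzyme LOX were at least 25.8-, 33.7- and 13.5-fold lower and the protease inhibitor TIMP1 differed by -4.56. SPARC was at least 1.17-fold higher and TAGLN differed by 0.60 (adjusted p = 0.0129, and 0.0831 without MCF10A-WHSC1L1s replicate 2, which leaves 1 higher member). Of 17 epithelial junction genes 9 were lower (10 adjusted over the list alone), 2 higher and 6 did not pass (camera adjusted p = 0.0296, and adjusted p = 0.46 with an estimated correlation). The tight junction gene CLDN1 was at least 17.9-fold lower, the desmosomal gene DSC2 at least 8.18-fold lower and PKP2 differed by -1.92, while CLDN3 was at least 19.2-fold higher. CRB3 was higher by 0.35 (adjusted p = 0.0409) and was not past the threshold without SUM-44 replicate 1 (0.109) or MCF10A-WHSC1L1s replicates 1 or 2 (0.148 and 0.167), each of which leaves 1 higher member, nor with background correction (0.0527) or an intensity trend (0.0703). Over genes above background on all 4 arrays the matrix and junction lists missed the threshold (0.119 and 0.114), and CRB3 did not pass either (limma adjusted p = 0.05).

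**Figure D2:**
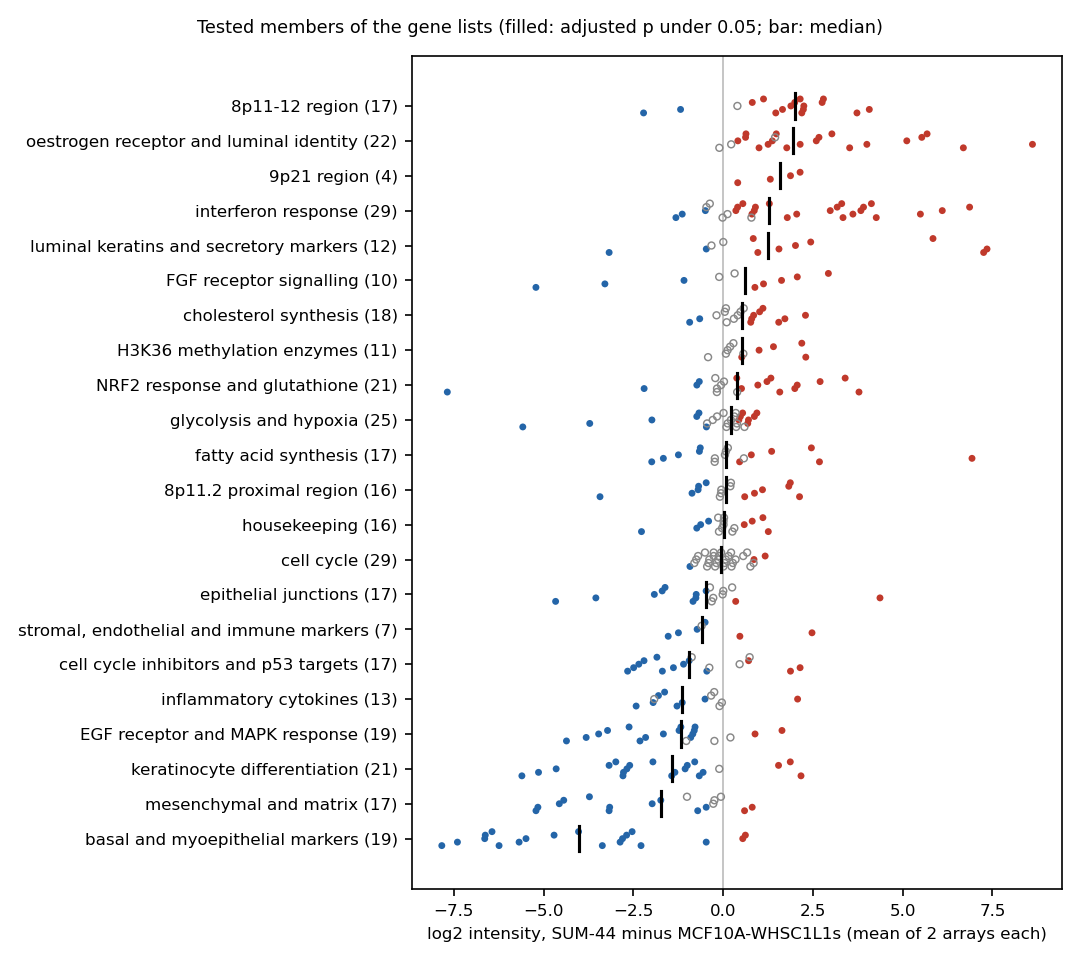
Log2 difference, SUM-44 minus MCF10A-WHSC1L1s, of each tested member of the 22 lists with at least 3 tested genes (number of genes in brackets), filled where the adjusted p is under 0.05, with the list median as a bar. The medians run from -4.03 for basal and myoepithelial markers to 2.00 for the 8p11-12 region.

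Genes of the 8p11-12 region were higher in SUM-44. Of 17 tested genes 14 were higher, 2 lower and 1 did not pass, also adjusted over the list alone, with a median of 2.00 (camera adjusted p = 1.63e-05, and adjusted p = 0.46 with an estimated correlation). PLPP5 was 16.8-fold higher (log2 difference 4.07, adjusted p = 1.76e-05), RAB11FIP1 13.2-fold, the trithorax-complex gene ASH2L 6.93-fold and the translation regulator EIF4EBP1 6.76-fold. LETM2 was lower (-2.21, adjusted p = 0.000371) and so was TACC1 (-1.18, adjusted p = 0.0145, and 0.105 without MCF10A-WHSC1L1s replicate 2, which leaves 1 lower member). Next to it, the proximal 8p11.2 region had 6 of 16 genes higher, 5 lower and 5 not past the threshold, also adjusted over the list alone (camera adjusted p = 0.715). There the Wnt antagonist SFRP1 was at least 8.01-fold lower, GOLGA7 was higher by 1.87 and GINS4 by 1.83, TCIM was at least 3.19-fold higher (at least 1.64- and 6.20-fold without SUM-44 replicate 1 or 2), and RNF170 was lower by a difference of -0.87. Without MCF10A-WHSC1L1s replicate 1 or 2, TCIM differed by 2.18 or 2.08, against 2.13 with all arrays, and GINS4 by 1.91 or 1.75. Both lost their calls there, where the spread is that of the SUM-44 arrays alone. These arrays read 9.93 and 8.02 for TCIM and 10.49 and 9.27 for GINS4. Without MCF10A-WHSC1L1s replicate 2 RNF170 differed by -0.76 and also lost its call. In both settings fewer members of the proximal region passed in each direction. The 2 regions were not tested against each other. All 4 tested genes of 9p21 were higher (camera adjusted p = 0.0115, adjusted p = 0.46 with an estimated correlation, and 0.0895 with no filter on dim probes), also adjusted over the list alone. The cell cycle inhibitors CDKN2A and CDKN2B and the neighbouring MTAP were at least 3.41-, 2.49- and 1.68-fold higher and were not above background in MCF10A-WHSC1L1s. KLHL9 was higher by 0.41 (adjusted p = 0.0314) and missed the threshold without any 1 of the 4 arrays (0.0642 to 0.166) and with an intensity trend (0.0504).

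**Figure D3:**
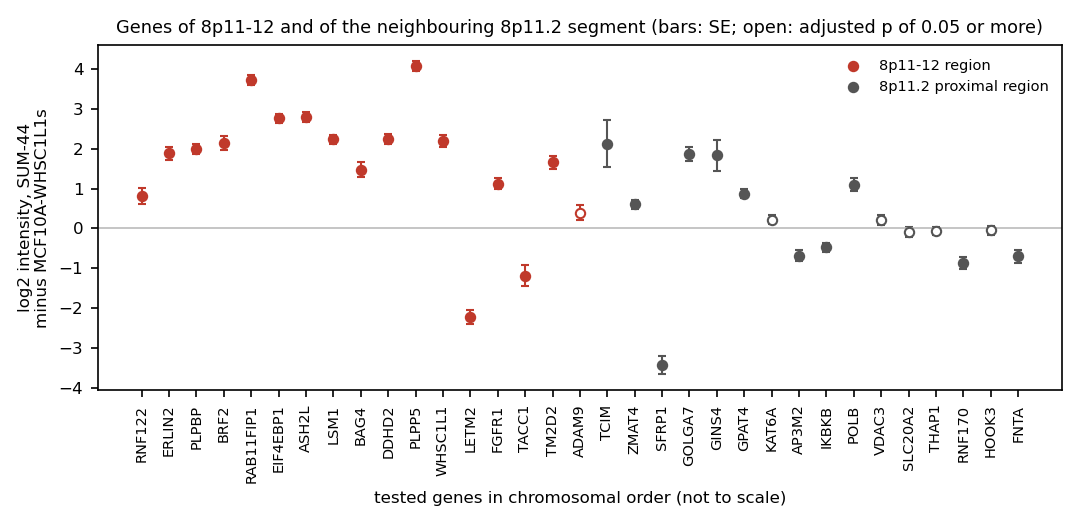
Log2 difference, SUM-44 minus MCF10A-WHSC1L1s, with its SE (bars) for tested genes of 8p11-12 and of proximal 8p11.2 in chromosomal order, open where the adjusted p is 0.05 or more. In 8p11-12, 14 of 17 genes are higher in SUM-44 and past the threshold, against 6 of 16 in the proximal region.

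Of 19 EGF receptor and MAPK response genes 14 were lower in SUM-44 (15 adjusted over the list alone), 2 higher and 3 did not pass (camera adjusted p = 0.000381, and adjusted p = 0.46 with an estimated correlation). Only the medium of MCF10A-WHSC1L1s lists EGF. EMP1 differed by -4.36, PHLDA1, above background on 1 of 2 SUM-44 arrays, by -3.81, the immediate early gene EGR1 by -3.47 and MYC by -3.22. EGR1 differed by 1.57 between the 2 SUM-44 arrays. The ERK inhibitor SPRED2 was higher by 0.89 and IER3 by 1.64 (adjusted p = 0.0251, and 0.151 and 0.109 without MCF10A-WHSC1L1s replicate 1 or 2, each leaving 1 higher member). Without SUM-44 replicate 1 the difference of IER3 was 0.95. Of 10 FGF receptor signalling genes 5 were higher (6 adjusted over the list alone), 3 lower and 2 did not pass (camera adjusted p = 0.484), and the median, 0.60, and the mean, -0.08, differ in sign. FGFR4 and FGF13 were at least 5.97- and 3.07-fold higher, FGFBP1 was at least 7.76-fold lower (at least 4.70- and 12.8-fold without MCF10A-WHSC1L1s replicate 1 or 2) and FLRT3 differed by -5.21. The other higher members were FGFR3 and SPRY1, besides FGFR1, and the other lower one was FGFRL1. Of 11 H3K36 methylation enzymes 5 were higher, WHSC1L1 and RIOX1 among them, 0 lower (1 at an unadjusted p of 0.05) and 6 did not pass, also adjusted over the list alone (camera adjusted p = 0.0152, and adjusted p = 0.46 with an estimated correlation). Medians were also set against the middle 95% of random lists of genes of like brightness. Those of the other lists called by camera at the preset correlation lay beyond it. Among lists not called, so did FGF receptor signalling (0.603, limits -0.536 to 0.559) and cell cycle inhibitors and p53 targets (-0.944, limits -0.459 to 0.453). Stromal, endothelial and immune markers did as well (-0.599, limits -0.583 to 0.593). The median of the H3K36 list, 0.519, lay within its limits (-0.551 to 0.524). SETMAR, SMYD2 and the demethylase KDM2A were higher by 2.30, 1.40 and 1.00, and without SUM-44 replicate 2, 1 member, SETD2, passed as lower.

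Most of the cell cycle list did not separate the lines. Of 29 genes 26 did not pass, 2 were higher and 1 lower, and adjusted over the list alone 0 were higher and 0 lower (3 and 3 at an unadjusted p of 0.05, camera adjusted p = 0.97). CENPA was higher by 1.17 (adjusted p = 0.023, and 0.0758 and 0.054 without SUM-44 replicate 2 or MCF10A-WHSC1L1s replicate 2), FOXM1 by 0.86 (adjusted p = 0.0203, and 0.07 and 0.0824 without SUM-44 replicate 1 or MCF10A-WHSC1L1s replicate 2), and CDT1 was lower (-0.92, adjusted p = 0.0145). Without MCF10A-WHSC1L1s replicate 2 CENPA differed by 0.71 and FOXM1 by 0.57. The counts moved with single arrays: 1 higher and 6 lower without SUM-44 replicate 1, 5 higher without MCF10A-WHSC1L1s replicate 1, and 0 higher and 5 lower without MCF10A-WHSC1L1s replicate 2. Replicates of a line differed in these genes, counted after the data were seen: 12 of 12 G1/S genes were higher in SUM-44 replicate 1 than in 2 (median 0.836), and 17 of 17 G2/M genes in MCF10A-WHSC1L1s replicate 1 (median 0.893). Of 17 cell cycle inhibitors and p53 targets 10 were lower, 3 higher and 4 did not pass, also adjusted over the list alone (camera adjusted p = 0.0595). The list passed without SUM-44 replicate 2 (0.0348) or MCF10A-WHSC1L1s replicate 2 (0.0444), with no filter (0.0136) and over genes above background on all 4 arrays (0.0114). ZMAT3, the inhibitor CDKN1A, the death receptor TNFRSF10B and TP53I3 differed by -2.66, -2.49, -2.35 and -2.20, and CDKN2A, CDKN2B and SUSD6 were higher.

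Of 29 interferon response genes 21 were higher in SUM-44, 3 lower (4 adjusted over the list alone) and 5 did not pass, with a median of 1.29, or 1.07 with 10 genes at their bounds (camera adjusted p = 6.11e-06, and adjusted p = 0.46 with an estimated correlation). BST2 (tetherin) and OAS2 were at least 59.1- and 12.0-fold higher and ISG15 differed by 5.49. IFI44L, above background on 1 of 2 SUM-44 arrays, was lower (-1.14), as was IFITM2 (-1.31, adjusted p = 0.0302, and 0.0734 and 0.0827 without SUM-44 replicate 1 or 2, and a difference of -0.72 without MCF10A-WHSC1L1s replicate 1) and HERC5. Of 13 inflammatory cytokine genes 7 were lower, 1 higher and 5 did not pass, also adjusted over the list alone (camera adjusted p = 0.0398, adjusted p = 0.479 with an estimated correlation, and 0.11 without SUM-44 replicate 2). The chemokines CCL20 and CXCL1 differed by -2.42 and -1.95, IL1A was at least 2.72-fold lower, and the receptor antagonist IL1RN was higher by 2.07. CCL20 was above background on 1 of 2 SUM-44 arrays and missed the threshold without MCF10A-WHSC1L1s replicate 1 (0.0549). The list's median, -1.14, is -0.61 with 4 genes at their bounds. The cytokine list also missed the threshold with no filter (0.0617) and over genes above background on all 4 arrays (0.371).

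Among metabolic genes, 8 of 18 cholesterol synthesis genes were higher (9 adjusted over the list alone), 2 lower and 8 did not pass (camera adjusted p = 0.0398, and adjusted p = 0.66 with an estimated correlation). Without SUM-44 replicate 2 the list had an adjusted p of 0.0511, and without MCF10A-WHSC1L1s replicate 2 it had 0.131 with 5 higher members. TM7SF2 differed by 2.29, HMGCS1 by 1.72, DHCR7 by 1.55 and SC5D by 1.11, the last not past the threshold without MCF10A-WHSC1L1s replicate 1 or 2 (0.0705 and 0.0832). MSMO1 and LSS were lower (-0.93 and -0.65), and without MCF10A-WHSC1L1s replicate 1 LSS was not past it (0.0726), leaving 1 lower member. Of 17 fatty acid synthesis genes 6 were higher, 5 lower and 6 did not pass, also adjusted over the list alone (camera adjusted p = 0.625). Besides THRSP, ACACB and ELOVL2 were at least 4.59- and 3.97-fold higher, while ACSL1 and the carboxylase ACACA differed by -1.99 and -1.66. Of 25 glycolysis and hypoxia genes 7 were higher, 6 lower and 12 did not pass, also adjusted over the list alone (camera adjusted p = 0.751), and the median, 0.22, and the mean, -0.28, differ in sign. The number higher was 11 without SUM-44 replicate 2, 1 without MCF10A-WHSC1L1s replicate 1 and 3 without MCF10A-WHSC1L1s replicate 2. The lactate dehydrogenase subunit LDHB was at least 37.9-fold lower, PFKP differed by -3.71 and ADM by -1.98, and SLC2A3 was at least 1.70-fold higher. Of 21 NRF2 response and glutathione genes 11 were higher, 4 lower and 6 did not pass, also adjusted over the list alone (camera adjusted p = 0.0642). It passed without SUM-44 replicate 1 (0.0317) or MCF10A-WHSC1L1s replicate 2 (0.0428), with no filter (0.0417) and with the mean of a gene's probes (0.0447). GPX2, above background on 1 of 2 MCF10A-WHSC1L1s arrays, PGD and GCLM were higher by 3.78, 3.40 and 2.70, and GSTO1 (-2.20), GSTP1, TKT and GPX1 were lower.

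Of 16 housekeeping genes 4 were higher, 4 lower and 8 did not pass, also adjusted over the list alone (camera adjusted p = 0.84). RPL13A differed by -2.27, TUBB by 1.26, GUSB by 1.11 and TFRC by 0.81. Without MCF10A-WHSC1L1s replicate 2 TUBB did not pass (0.0727) and 2 genes were higher and 2 lower. Of 18 cancer-testis antigen genes with a probe 0 were above background on both arrays of a line. Of 24 stromal, endothelial and immune markers with a probe 7 were tested, of which 2 were higher, 4 lower (5 adjusted over the list alone) and 1 did not pass (camera adjusted p = 0.508). VWF was at least 4.32-fold higher and COL1A1 at least 1.09-fold (adjusted p = 0.0163, and 0.0712 and 0.106 without MCF10A-WHSC1L1s replicate 1 or 2, each leaving 1 higher member). CD14 was at least 1.85-fold lower, DCN at least 2.40-fold (0.0481, and 0.108 and 0.118 without SUM-44 replicate 1 or 2, and 0.0735 with no filter, and at least 1.37- and 4.23-fold without MCF10A-WHSC1L1s replicate 1 or 2), and CD68 differed by -0.72 (0.00717, and 0.0642 without MCF10A-WHSC1L1s replicate 1, which leaves 2 lower members). PECAM1 was the other lower gene.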

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

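The median scaling, the 95th percentile of background and the use of the mirrored tail were chosen after the data were seen, and the other settings were planned. Counts of 2614 higher and 2765 lower genes became 2659 and 2815 with background correction (normexp, offset 50), 2678 and 2692 with equal medians, 2674 and 2835 with no filter, and 2671 and 2814 with an intensity trend. The number of genes at least 2-fold higher fell to 759 and lower to 681 over genes above background on all 4 arrays, where fewer genes are tested. Testing a minimum difference of 1 within the model gave 597 higher and 508 lower. Leaving out 1 array gave 1604 to 2519 higher and 1567 to 2639 lower genes, with fewer samples. Probes seen in 1 line became 926 and 881 with the looser limit used for both lines. With an estimated correlation, lists called by camera went from 7 higher and 6 lower to 0 and 0. That form also missed the shifted list of the simulation. Over genes above background on all 4 arrays the lower lists called fell to 3. With that filter the higher lists also lost luminal keratins and secretory markers (0.119), and 9p21 had too few genes to test. Camera's direction turned, with no call, for cell cycle (adjusted p = 0.947 with no filter), and for fatty acid synthesis (0.74) and FGF receptor signalling (0.633) over genes above background on all 4 arrays. Leaving out 1 array, it turned for cell cycle without SUM-44 replicate 1 or MCF10A-WHSC1L1s replicate 2 (0.165 and 0.171; range 0.0776 to 0.267 over the 4 arrays), and without SUM-44 replicate 1 for glycolysis (0.977; range 0.43 to 0.977) and housekeeping (0.813; range 0.43 to 0.927). The cause was not tested. The labels do not say what samples with the same replicate number share. With 2 pairs, the differences between replicates 1 and 2 of the lines correlated at 0.235 across probes, and with the number as a block 2809 genes were higher and 2946 lower, and the p53 list passed (0.041). Median scaling and uncorrected signal of the scanner table, and the slide as a block, were not run, since the columns match no sample and no slide is given. Groups of 2 are too small to count other splits of the samples. Signal near background limits the folds of genes seen in 1 line.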

Other observations

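The tests of WHSC1L1 and of the neighbouring genes were chosen after their results were seen. For the differences between SUM-44 replicates, the lists were written after the 60 largest had been seen, and the tests on their other members were set before those values were computed, though the replicate spread of some had been seen. The counts of cell cycle genes between replicates were made after the data were seen.

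Mean differences of runs of neighbouring genes stood out in several places besides 8p11-12. In RefSeq order, over 9689 genes, 12 runs of 15 neighbouring genes had a mean beyond the limit that 95% of 1000 shuffled orders stayed within, 8 higher in SUM-44 and 4 lower. The furthest ran from THAP12 to GAB2 and held RSF1, INTS4, CLNS1A and THRSP, with 13 of 15 genes higher and a mean of 2.11 on the log2 scale. The run from ERLIN2 to TM2D2, that of 8p11-12, had a mean of 1.79 (permutation p = 0.003, with 13 higher and 2 lower). Among the lower runs, that from JOSD2 to ZNF350 held 5 kallikrein genes and 12 of 15 genes lower. Those from IGF2BP2 to TMEM207 and from LAMB1 to MET had 9 of 15 genes lower each, and 0 and 2 higher, with means of -1.59 and -1.48 but medians of -0.64 and -0.69.

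WHSC1L1 was lower in the line transduced with it. Exchanged labels of the 2 lines would put the 8p11-12 genes low on the arrays labelled SUM-44, where 14 of 17 were higher. A factor common to the genes of an array would move housekeeping genes by about as much as WHSC1L1 (2.19). Their median was 0.012 (SD 0.83, 16 genes, highest 1.26, RPL13A -2.27). The arrays share the same sorted values, so such a factor was already removed, and this median cannot decide on scaling. Probes outside the transduced sequence would miss the transgene and could leave this pattern. The short-isoform probe differed by 0.88 more than the long-isoform probes. Those lay near background in MCF10A-WHSC1L1s, at 7.40 and 7.41, which compresses their differences, so the 0.88 cannot decide. The position of the probes is not given in the sources used here. Probes that miss the transgene therefore cannot be told apart from a low transgene level, and a higher level in SUM-44 through amplification also stays open.

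The run from THAP12 to GAB2 had a median of 2.21 against 1.25, the highest window median that 95% of shuffled orders stay within, so a few strongly changed genes do not carry it. A window mean as high came up by chance with p = 0.000999, the smallest that 1000 permutations can give. The run with the TFF genes, from SH3BGR to SLC37A1, had a median of 1.59 against the same limit. A candidate explanation is a difference in copy number between the lines. Copy number was not measured here, and shared regulation of neighbours stays open.

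In SUM-44, CCN2 was higher in replicate 1 by 5.41 on the log2 scale, ID3 by 4.33 and ID1 by 2.99, and replicate 1 minus 2 was -3.53 for DDIT4, -2.61 for GATA3 and -1.84 for ATF4. Of ATF4 response genes outside the 60 largest differences, 23 of 25 were higher in replicate 2, with a median of -0.485 (middle 95% of 10000 random lists -0.141 to 0.108), which argues against noise of single probes, and in MCF10A-WHSC1L1s 21 of 25 were (-0.169, random lists -0.098 to 0.085). Immediate early genes outside the 60 gave 0.162 with 11 of 17 higher in replicate 1, just beyond random lists (-0.161 to 0.133), and in MCF10A-WHSC1L1s -0.038 with 8 of 17 higher, within them (-0.128 to 0.098). Of G1/S genes outside the 60, 11 of 11 were higher in replicate 1 of SUM-44 (0.83, random lists -0.182 to 0.179) and 10 of 11 in MCF10A-WHSC1L1s (0.058, within -0.146 to 0.122, but 0.138 over all 12 genes, beyond -0.145 to 0.11), and of G2/M genes 10 of 17 (0.229, beyond -0.158 to 0.148) and 17 of 17 (0.893, beyond -0.133 to 0.095). A batch shared by samples of 1 number, the state of the cells and processing of the RNA all stay open, and no biological explanation was tested.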
